A study of Mus musculus with 9 samples.

How the data were processed

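Whole tibialis anterior muscle of 2-month-old mice was profiled on 9 Affymetrix Clariom S mouse arrays, 3 for each of 3 genotypes: control, MCU knockout and MCUb knockout. Per the labels' protocols, muscles were flash-frozen, total RNA was extracted with Trizol and checked on a Bioanalyzer, and biotin-labelled targets were made with a 3' IVT Pico kit. The deposited table holds 1 log2 value per probe set and array, made with Affymetrix Expression Console per the submitters' processing notes. The program's version, its summarisation method, its normalization and the base of the logarithm were not given in the sources used here. Values ran from 2.46 to 19.9 and were read as log2, so every fold below rests on that reading. How the unstated normalization shaped the values is not known. The array medians lay between 5.51 and 5.60, under the background limits of 5.87 to 5.92 described below. They therefore cannot show whether the signal of an array was shifted as a whole. Harvest time, sex and litter of the mice were likewise not given in the sources used here.

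Each array carried 28846 values. Of these, 6640 belonged to control features and were left out of the tests, which left 22206 probe sets. A table of platform annotation named 19572 of them with 1 gene symbol, 0 with several and 2634 with none. All 19572 were matched to current symbols through their gene identifiers in the RefSeq table of GRCm38.p6, giving 19505 distinct symbols. For the 55 genes with several probe sets, the probe set with the highest mean over all arrays was read. The genome build behind the array design was not named, so the reference table served only for names, chromosomes and the order of neighbouring genes. Mcub was not analysed here. A probe set counted as above background on an array when it exceeded the 95th percentile of 23 background sets of that array, which lay between 5.87 and 5.92. A probe set not above background on any array of a group has only a bound there, and its fold is given as at least the brighter group's mean over the dimmer group's limit.

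Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the deposited log2 values as they were. All 9 arrays entered 1 fit of 3 group means, with 6 residual degrees of freedom and a prior worth 5.06 more, and no covariate. P-values were adjusted by Benjamini-Hochberg over the 22206 probe sets, with a threshold of 0.05. Comparisons were MCU knockout with control, MCUb knockout with control, and the knockouts with each other, the last being the direct test of whether they differ. Log2 changes carry the standard error (SE) of the fit, and group means the standard deviation (SD) with n = 3 arrays throughout. The labels do not say that the 3 samples of a group came from separate animals, so the p-values measure the spread between these samples, which may be in part technical. The mean level of the Y-linked genes Uty and Kdm5d argues against 1 animal for a whole knockout group. It was 3.58 on MCU knockout replicate 1 against 7.56 and 7.24, and 7.80 on MCUb knockout replicate 1 against 3.01 and 3.58. The Y-linked gene Eif2s3y, not well above background, did not follow it. For the controls the question stays open. The number of arrays limits the precision: at the median SE of 0.23, a log2 change had to reach 1.43, 1.75 and 1.40 to pass in the comparisons in that order.

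Gene lists were tested with camera (limma) at a preset correlation between genes of 0.01, adjusted over the 32 lists within each comparison. Each was tested again with the correlation estimated from the list's own residuals, and with fry, which asks whether a list's genes move one way on balance or, in its mixed form, in either direction. The lists covered mitochondrial calcium transport and energy metabolism, stress and redox responses, the mitochondrial ribosome and the proteasome, calcium handling, fibre type, atrophy and denervation, 9 groups of markers of other cell types and of blood, the interferon response, the circadian clock, immediate early genes and sex-linked genes. The ribosome and proteasome lists were taken by symbol prefix, which brought in Psmc3ip, no proteasome subunit. The groups, the tests, the lists, the other settings tried and the rule for naming genes were fixed before the data were examined. By that rule the text names Mcu, then the 8 highest and 8 lowest changes past the threshold with groups that do not overlap in each comparison with control, and 6 and 6 between the knockouts. Short lists were filled by smallest p, and these genes are given as not past the threshold. Up to 3 members of each list with the smallest p are named besides, and symbols of predicted genes were skipped. Genes named outside the rule are said to be chosen after their values were seen.

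The other settings, all in that plan, were a filter on dim probe sets, quantile normalization, centring of each array on its median, an intensity trend with a robust prior, array quality weights, a fit of the 2 groups alone, the replicate number as a block, a looser threshold of 0.1, a fold minimum of 1.5, probe sets with 1 symbol only, and each array left out in turn. Chosen after seeing the data, the mean level of the Y-linked genes Uty and Kdm5d was added as a covariate, as was a fit of the 6 arrays where it was low, and the uniporter list was tested without Mcu. The procedure was tested on simulated data for the comparison of MCU knockout with control, in 20 simulations of 22206 probe sets. In each, 200 were changed, all drawn from probe sets with a mean above the median of all. It found 95.2% of 4-fold changes, 29.7% of 2-fold changes and 2.09% of 1.5-fold changes, with 5.55% of its calls false. Detection among dimmer probe sets was not tested. A list shifted by 0.5 on the log2 scale was found in 19 of 20 simulations with the preset correlation and in 16 with the estimated one. The simulated noise was independent between genes, unlike that of the fatty acid oxidation list, with an estimated correlation of 0.344. So these shares do not show how either setting does on correlated lists. For the same comparison, the test of chromosomal neighbours on 19505 genes passed in 20 of 20 simulations with planted pairs and in 1 of 20 without. Plots were drawn with matplotlib 3.10.9.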

Results

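The uniporter carries calcium into the mitochondrial matrix. MCU forms its pore, and MCUb is a paralogue of MCU that joins the same complex. The series asks what MCUb does for oxidative phosphorylation, and its arrays compare tibialis anterior, a fast-twitch muscle of the lower leg, of mice without MCU and of mice without MCUb with control muscle. Each genotype was measured on 3 arrays, all from mice 2 months old on a C57/BL6 background per the labels. Between 45.3% and 45.9% of the probe sets of an array lay above background. The mean correlation of an array with the other 8 was between 0.978 and 0.988, lowest for control replicate 3. This array stood apart from the rest: the first principal component, with 28.1% of the variance, put it at -70.8 and the other 8 between -20.3 and 21.9, and its array quality weight in limma was 0.436 against 0.671 to 1.31 for the others. It enters both comparisons with control.

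Mcu (probe set TC1000002212.mm.2, chromosome 10) had log2 levels of 10.38, 10.96 and 10.46 on the control arrays and of 6.80, 6.98 and 7.06 on the MCU knockout arrays. Its mean fell from 10.60 ± 0.31 (SD, n = 3) to 6.94 ± 0.13, a log2 change of -3.65 (SE 0.20), or 12.6-fold lower, with an adjusted p of 3.47e-05 in limma. An exact permutation test, two-sided, gave p = 0.1, the smallest that 3 arrays against 3 allow. The remaining signal was above background on every MCU knockout array, and where the probes lie relative to the deleted part is not known. In the MCUb knockout Mcu stood at 10.86 ± 0.18, a log2 change of 0.26 (SE 0.20, adjusted p = 0.746). Mcub was not analysed here, so the MCUb knockout label has no check from its own transcript.

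The Y-linked genes Uty and Kdm5d, which only male tissue transcribes, were not level across the arrays. Their mean log2 level was 7.56 and 7.24 on MCU knockout replicates 2 and 3 and 7.80 on MCUb knockout replicate 1. On the other 6 arrays, all controls among them, it lay between 3.01 and 3.89. Eif2s3y, a further Y-linked gene, did not follow it: its log2 level was 3.75, 3.01 and 3.09 on these 3 arrays and between 2.75 and 3.04 on the other 6, and it was not well above background on any array. The labels do not give the sex of the mice. For 4 of the 32 gene lists, the mean level on these 3 arrays lay outside the range of the other 6. Fatty acid oxidation and lymphocyte genes were lower, by a gap of 0.20 and 0.04 on the log2 scale. Only 2 of the 13 measured lymphocyte genes were above background on any array. Redox defence and sex-linked genes were higher, by 0.0072 and 2.22. The same held for 20 of the 224 genes that the naming rule picked, among them Casq2, Myh2, Idh2, Ddit3 and Eci1, which were lower. The sex-linked list, and Uty and Kdm5d among the 20, separate by construction, since Uty and Kdm5d defined the 3 arrays. The share that chance gives was not worked out, and most of the 224 were picked for a small p or a large change.

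A small set of genes was strongly raised in muscle without MCU. Serpina3n, a secreted inhibitor of serine proteases, rose from 4.12 ± 0.09, not well above background, to 7.88 ± 0.24, at least 3.95-fold (adjusted p = 6.28e-05). Myorg, a glycosidase with a role in muscle differentiation, rose 6.78-fold from 10.93 ± 0.60 to 13.69 ± 0.16 (SE of the log2 change 0.29, adjusted p = 0.00336). Snx9, a sorting nexin of endocytosis, rose 4.11-fold from 9.22 ± 0.18 to 11.26 ± 0.05 (adjusted p = 0.00116), and Rhobtb3 rose 3.94-fold from 10.49 ± 0.22 to 12.47 ± 0.22 (adjusted p = 0.00226). Probe sets for Dynlt1a, Dynlt1b, Dynlt1c and Dynlt1f, copies of a dynein light chain, rose by 1.99 to 2.39 on the log2 scale (adjusted p between 0.00116 and 0.00353). These copies are nearly identical, so how many of them changed is uncertain.

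Among the genes that fell in the MCU knockout, Gadd45gip1, a component of the mitochondrial ribosome, went from 8.68 ± 0.21 to 6.95 ± 0.19, 3.31-fold lower (log2 change -1.73, SE 0.19, adjusted p = 0.00336). Gfer, a sulfhydryl oxidase of the mitochondrial intermembrane space that drives oxidative folding of imported proteins, fell 3.10-fold from 10.12 ± 0.37 to 8.49 ± 0.18 (SE 0.25, adjusted p = 0.0319). Plbd1, a phospholipase B-like protein, fell 4.28-fold (log2 change -2.10, SE 0.26, adjusted p = 0.00662). Rsph3a, a radial spoke protein of cilia, fell by 1.82 (SE 0.20, adjusted p = 0.00346), and Pdlim1, a PDZ-LIM protein that binds alpha-actinin, by 1.78 (SE 0.25, adjusted p = 0.0205). Vmn2r29, a vomeronasal receptor gene, fell from 7.68 ± 0.35 to 5.73 ± 0.24 (adjusted p = 0.00649), where 1 of the 3 knockout arrays was above background. The orphan receptor gene Gpr19 fell from 6.67 ± 0.48 to 4.92 ± 0.05, not well above background, at least 1.70-fold (adjusted p = 0.0361).

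In all, 31 probe sets passed the threshold between MCU knockout and control, 14 higher and 17 lower, 29 of them named. The smallest change among them was 1.20 on the log2 scale. At an unadjusted p under 0.05 there were 2243 probe sets, where chance gives 1110.3. That number depended on single arrays of both groups. It was 1755 without control replicate 3, 1725 without MCU knockout replicate 2 and 1701 without MCU knockout replicate 3. It rose only without control replicate 2, to 3684. Control features of the arrays had a similar excess, 626 of 6640 where chance gives 332. In 2978 (13.4%) of the probe sets tested the groups did not overlap, where chance gives 10%. With the Y-linked level as a covariate 16 passed, and on the 6 arrays where it was low, with a single MCU knockout array among them, 0 passed in limma (1090 at an unadjusted p under 0.05). On those 6 arrays the 31 changes were 0.835 to 1.22 times their size over all 9 arrays, and their median SE went from 0.22 to 0.32. Their sign could not turn there, because in all 31 no MCU knockout array overlapped with the same controls. Those arrays also served to pick the 31, so the sizes are no independent check. Snx9 was at 2.10 (SE 0.30) there, Rhobtb3 at 1.88 (SE 0.31) and Gadd45gip1 at -1.75 (SE 0.29). The count past the threshold was 20 without MCU knockout replicate 3 and 98 without control replicate 2.

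**Figure D1:**
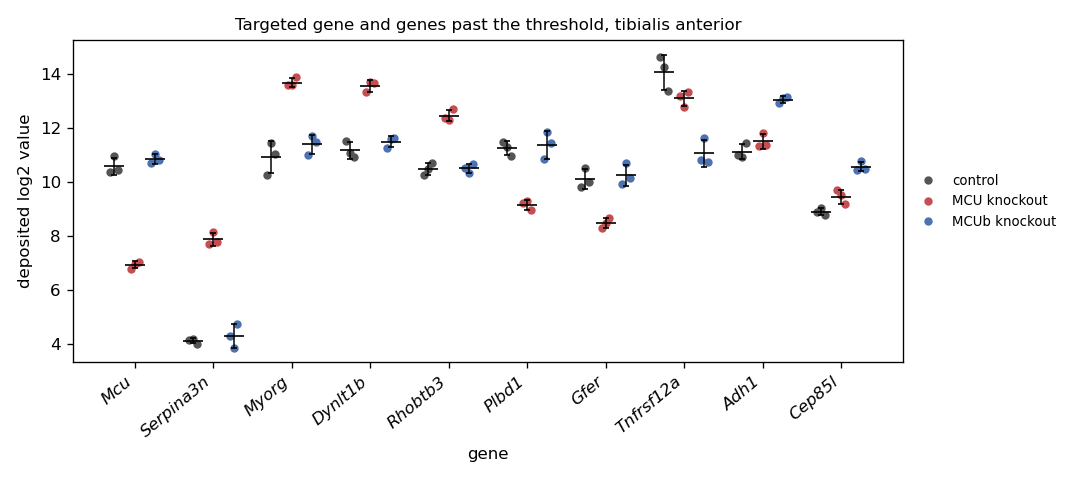
Deposited log2 values (vertical axis) of 10 genes on each of the 9 arrays, by genotype; points are arrays, and bars show the mean and SD of 3 arrays. Mcu lies at 6.94 in the MCU knockout against 10.60 in control, Serpina3n and Tnfrsf12a separate the knockouts, and Adh1 and Cep85l are highest in the MCUb knockout.

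Of the 32 gene lists, 2 passed between MCU knockout and control by camera. Genes of mitochondrial fatty acid oxidation were lower as a list in the MCU knockout: 17 of the 20 measured members lay below control, with a median log2 change of -0.28 (camera adjusted p = 0.012, and adjusted p = 0.92 with an estimated correlation). Hadha, a subunit of the trifunctional protein, had a change of -0.75 (SE 0.25, adjusted p = 0.373), Eci1 one of -0.67 (adjusted p = 0.352) and Acss1, mitochondrial acetyl-CoA synthetase, one of -1.64 (SE 0.60, adjusted p = 0.412). In limma 0 members passed over all probe sets and 0 adjusted over the list alone, while 3 fell and 0 rose at an unadjusted p under 0.05. This list moved with the Y-linked level, which was high on 2 of the MCU knockout arrays and on no control: the mean log2 level of its genes was at most 12.11 on the 3 arrays with high levels and at least 12.31 on the others. With that level as a covariate its adjusted p was 0.771, within a range of 4.16e-05 to 0.927 over 16 alternatives. It was also lost without control replicate 3 (0.0778), MCU knockout replicate 2 (0.115) or MCU knockout replicate 3 (0.162).

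The respiratory chain list did not pass in the MCU knockout. Of 75 measured nuclear-encoded subunits, 30 lay above control and 45 below, with a median of -0.05 (adjusted p = 0.841). Ndufa3 of complex I stood at 14.07 ± 0.19 against 15.12 ± 0.23 (log2 change -1.05, SE 0.19, adjusted p = 0.0831), and it alone fell when adjusted over the list alone. Ndufa7 (-0.67) and Cox7a2 (0.76) did not pass. In the list of the uniporter complex and calcium transport, 11 genes were measured, with a median of -0.03 (adjusted p = 0.761). Only Mcu passed there, over all probe sets and adjusted over the list alone, while Vdac2 (0.30) and Mcur1 (-0.22) did not. The citrate cycle and pyruvate dehydrogenase list had a median of 0.04 (adjusted p = 0.841), with Mpc1 at 0.56, Idh2 at -0.87 and Pdp1 at 0.71, none past the threshold.

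Other metabolic and stress lists did not pass in the MCU knockout by camera. Glycolysis and glycogen had a median of 0.01 (0.841 as the adjusted p), fatty acid uptake and PPAR targets -0.18 (0.834), fatty acid and sterol synthesis -0.17 (0.806), and amino acid and ketone catabolism -0.01 (0.841). By fry, fatty acid and sterol synthesis passed for change in either direction (adjusted p = 0.0418) but not for a shift one way (0.869). Pdk4, the kinase that shuts off pyruvate dehydrogenase, was at 1.01 (SE 0.36, adjusted p = 0.404), and Bdh1, of ketone body metabolism, fell by 1.21 when adjusted over the list alone but not over all probe sets (adjusted p = 0.248). The mitochondrial ribosome, with 54 of 76 members below control, had a median of -0.18 (adjusted p = 0.105, and 0.0120 without control replicate 1), with Mrps34 at -0.93 and Mrps21 at -0.73. Mitochondrial chaperones and proteases had a median of -0.00 and mitochondrial biogenesis and dynamics one of 0.06, against a mean of -0.10 (adjusted p = 0.841 for each). The integrated stress response stood at 0.02 (0.956), redox defence at 0.08 (0.841) and the proteasome at -0.04 (0.841). Ddit3, a stress-induced transcription factor, was at -0.82 (adjusted p = 0.308).

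The contractile lists did not pass either, and single genes spread widely between arrays. Casq2, the slow-fibre calsequestrin, stood at 9.26 ± 1.10 against 11.58 ± 0.13 in control (log2 change -2.32, SE 0.53). It fell when adjusted over the list alone but not over all probe sets (adjusted p = 0.204). Both Casq2 and the IIa myosin Myh2 moved with the Y-linked level. Casq2 was at most 9.89 on the 3 arrays with high levels and at least 10.43 on the other 6, and Myh2 at most 14.27 and at least 15.47. With that level as a covariate their changes were -1.30 (adjusted p = 0.432) and -0.73 (adjusted p = 0.560). Myl2, a slow myosin light chain, was at -2.00 (adjusted p = 0.361) and Myh2 at -2.09 (SE 0.65, adjusted p = 0.349). The slow fibre list had a median of 0.15, a mean of -0.44 and a downward test (adjusted p = 0.841). Its mean level was 9.12, 8.52 and 8.39 on the arrays with high Y-linked levels and between 9.12 and 9.49 on the others. The fast fibre list had a median of 0.11, a mean of -0.02 and an upward test (0.596). Excitation-contraction coupling had a median of 0.17 (0.244), with Stim1, the calcium sensor of store-operated entry, at -0.83 (SE 0.21, adjusted p = 0.261). Atrophy genes had a median of -0.12 (0.834), with Fbxo32 at 0.82, and denervation and regeneration genes one of 0.04 (0.841).

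Markers of other cell types of the muscle did not pass as lists over all 9 arrays, and some passed with 1 array left out. Fibroblast and matrix genes had a median of 0.16 (adjusted p = 0.106), with Col5a1 at 1.17 (SE 0.32, adjusted p = 0.306), and passed as higher without control replicate 1 (camera adjusted p = 0.0120) or MCU knockout replicate 1 (4.16e-05). Endothelial and pericyte genes had a median of -0.04 (0.596) and passed as lower without control replicate 3 (0.0275). Over all arrays Rgs5, a pericyte marker, fell by 0.83 adjusted over the list alone but not over all probe sets (adjusted p = 0.247). Macrophage and neutrophil genes had a median of 0.20 and a mean of -0.03 (0.761), lymphocyte genes a median of -0.16 (0.596) and the interferon response -0.07 (0.841). Adipocyte genes had a median of -0.07 and a mean of 0.06 (0.841), with Car3 higher by 1.15 adjusted over the list alone (adjusted p = 0.306 over all probe sets). Tendon genes stood at -0.04 (0.855), satellite cell genes at -0.10 (0.841) and Schwann cell genes at -0.06 (0.841). Over 4 measured erythroid and blood genes the median was 0.07 (0.855), and Alas2 of haem synthesis fell by 0.77 adjusted over the list alone (adjusted p = 0.332 over all probe sets). Immediate early genes had a median of 0.02 (0.841). The sex-linked list of 3 measured genes did not pass (0.105), except as higher without MCU knockout replicate 1 (0.00777) or MCUb knockout replicate 1 (0.0179). Its members are the Y-linked genes given above, not well above background on the control arrays, with Uty at 6.80 ± 3.09 against 3.59 ± 0.46.

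Circadian clock genes were lower as a list in the MCU knockout, with 12 of 16 below control and a median of -0.37 (camera adjusted p = 0.00528, and adjusted p = 0.82 with an estimated correlation). Ciart, a clock repressor, was at -1.14 (SE 0.26, adjusted p = 0.204), the output gene Dbp at -0.87 (SE 0.20, adjusted p = 0.208) and Cry2 at -0.82 (SE 0.20, adjusted p = 0.251). Over all probe sets 0 clock genes passed in limma, with 6 lower at an unadjusted p under 0.05, and these 6 (Per2, Cry2, Ciart, Bhlhe40, Dbp and Nr1d1) fell adjusted over the list alone. By fry the list had an adjusted p of 0.128 for a shift one way and of 8.66e-05 for change in either direction. Fry with a shift one way passed only the uniporter list (0.0366), which holds the deleted gene and had an adjusted p of 0.869 without Mcu. For change in either direction it passed that list too (1.04e-06, and 0.661 without Mcu). Clock genes named here and below beyond the 3 of smallest p in a comparison were chosen after their values were seen.

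Few genes passed the threshold between MCUb knockout and control. Adh1 (TC0300001409.mm.2), the class I alcohol dehydrogenase, which also oxidises retinol, rose 3.80-fold from 11.13 ± 0.27 to 13.06 ± 0.13 (log2 change 1.93, SE 0.21, adjusted p = 0.0152). Cep85l, a centrosomal protein, rose 3.17-fold from 8.91 ± 0.13 to 10.57 ± 0.17 (SE 0.19, adjusted p = 0.0173). Tnfrsf12a (TC1700001598.mm.2), the receptor for the cytokine TWEAK, fell 8.06-fold from 14.08 ± 0.65 to 11.07 ± 0.49 (log2 change -3.01, SE 0.34, adjusted p = 0.0152). Nr1d1, the clock repressor REV-ERB alpha, fell 4.06-fold from 13.73 ± 0.40 to 11.71 ± 0.40 (SE 0.27, adjusted p = 0.0462). The remaining probe set, TC0Y00000223.mm.2, has no gene name in the sources used here and fell from 13.44 ± 0.51 to 9.82 ± 0.44 (adjusted p = 0.0152), an identifier chosen after its values were seen.

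Further genes with groups that did not overlap were not past the threshold in the MCUb knockout. Clec3b, which encodes tetranectin, was at 1.69 (SE 0.28, adjusted p = 0.163), the chloride transporter gene Clcn3 at 1.30 and Pus10 at 1.13. The zinc finger gene Zfp472 and Rpp38 were above background on 1 MCUb knockout array and on 0 control arrays, and Nfkbiz on 1 control array and 0 MCUb knockout arrays, so no fold is given for them (adjusted p of 0.163, 0.226 and 0.163). Ska2, a spindle protein, was at least 1.25-fold higher (6.22 ± 0.04 against 5.14 ± 0.11 in control, not well above background there, adjusted p = 0.127). On the lower side, Xirp1, an actin-binding protein of striated muscle, stood at -1.88 (adjusted p = 0.163), monoamine oxidase gene Maob at -1.60 (0.165), Dhrs3, a retinal reductase, at -1.47 (0.179), Pias4 at -1.39 (0.239) and Entpd1, an ectonucleotidase, at -1.29 (0.26).

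Between MCUb knockout and control 5 probe sets passed, 2 higher and 3 lower. At an unadjusted p under 0.05 there were 1802, where chance gives 1110.3, and among control features 567 of 6640, where chance gives 332. The first of these depended on single arrays of both groups. It was 1389 without control replicate 3 and 1395 to 1436 without an MCUb knockout array, and it rose only without control replicate 2, to 3339. In 2832 (12.8%) of the probe sets tested the groups did not overlap, where chance gives 10%. The count was 0 in limma without control replicate 1, MCUb knockout replicate 1 or MCUb knockout replicate 3 (1649, 1395 and 1436 at an unadjusted p under 0.05), 2 without MCUb knockout replicate 2, 3 without MCU knockout replicate 2 and 20 without control replicate 2. It was 1 in a fit of the 6 arrays of these groups and 0 on the arrays with low Y-linked levels (1117 at an unadjusted p under 0.05), where the 5 changes were 0.958 to 1.11 times their size over all arrays.

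No list passed for a shift one way in the MCUb knockout: 0 of 32 by camera, 0 with an estimated correlation and 0 by fry, against 7, 0 and 4 at an unadjusted p under 0.05. For change in either direction fry passed 1 list, the clock genes (adjusted p = 1.18e-07). Nuclear-encoded respiratory chain genes, the group the series is about, had 31 members above control and 44 below, with a median of -0.08 (adjusted p = 0.827). Cox7a2 was at 0.69, Ndufab1 at 0.67 and Ndufs5 at 0.60, none past the threshold. The lowest adjusted p, 0.102, was shared by fatty acid oxidation (15 of 20 below control, median -0.28), glycolysis and glycogen (18 of 27 above, median 0.19) and endothelial and pericyte markers (12 of 15 below, median -0.28). Ldha, lactate dehydrogenase, was at 0.72 (SE 0.31, adjusted p = 0.594), Cldn5 of endothelial junctions at -1.21 (SE 0.33, adjusted p = 0.477) and Kdr, the VEGF receptor, at -1.09 (0.555). Endothelial and pericyte genes passed as a list with the filter on dim probe sets, after quantile normalization, on the arrays with low Y-linked levels and without control replicate 3 or MCUb knockout replicate 1. Fatty acid oxidation passed with that filter, and glycolysis without MCUb knockout replicate 3.

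Among other MCUb knockout lists, excitation-contraction coupling had a median of 0.12 (adjusted p = 0.171), with Camk2d, a calcium-dependent kinase, at 1.53 (SE 0.38, adjusted p = 0.469). The uniporter list had a median of 0.07 (0.225), with Micu2, a calcium-sensing gatekeeper of the uniporter, at 0.90 (SE 0.44, adjusted p = 0.62). The fusion gene Opa1 was at 0.75 (0.53), Pdp1, the phosphatase that activates pyruvate dehydrogenase, at 0.95 (0.527) and Ucp3 at -1.07 (0.556). All 9 measured Schwann cell genes lay below control, with a median of -0.24 (0.19), but only 4 of them were above background on any array. Clock genes had a median of 0.35 and a mean of 0.12 (0.225). There Nr1d1 alone passed over all probe sets, and adjusted over the list alone Per2, Ciart and Hlf rose while Arntl and Nr1d1 fell (Ciart 1.22, SE 0.26, adjusted p over all probe sets 0.385).

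Set directly against each other, the knockouts differed in 35 probe sets, 14 higher in the MCU knockout and 21 lower. Serpina3n stood at 7.88 ± 0.24 in the MCU knockout and 4.32 ± 0.45 in the MCUb knockout, not well above background there, at least 3.97-fold apart (adjusted p = 0.00011). Tnfrsf12a was 4.13-fold higher in the MCU knockout (13.11 ± 0.28 against 11.07 ± 0.49, adjusted p = 0.0489). Clec3b was 5.86-fold lower in the MCU knockout (6.22 ± 0.33 against 8.77 ± 0.57, SE 0.28, adjusted p = 0.00339), above background on 2 of its 3 arrays. Mcu differed by -3.91 (SE 0.20, adjusted p = 1.65e-05), Myorg by 2.29 (0.00959), Rhobtb3 by 1.96 (0.00216), Plbd1 by -2.22 (0.00551), Rsph3a by -1.91 (0.00309) and Gfer by -1.77 (0.0163). Dynlt1b and Dynlt1c, near-identical copies, differed by 2.06 and 1.95.

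Between the knockouts 1266 probe sets had an unadjusted p under 0.05, close to the 1110.3 that chance gives. In 2838 (12.8%) the groups did not overlap, where chance gives 10%. The count past the threshold was 61 with array quality weights, 3 on the arrays with low Y-linked levels (where the 35 differences were 0.666 to 1.30 times their size over all arrays), 13 without MCU knockout replicate 3, 19 without MCUb knockout replicate 3 and 23 without MCUb knockout replicate 2.

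Clock genes had the lowest camera p of the lists between the knockouts: 12 of 16 were lower in the MCU knockout, with a median of -0.66 (camera adjusted p = 9.38e-06, and adjusted p = 0.22 with an estimated correlation). Ciart was 5.15-fold lower (6.05 ± 0.47 against 8.42 ± 0.26, adjusted p = 0.0037), Per2 differed by -1.75 (SE 0.26, adjusted p = 0.0265), and Cry2 by -1.30 (SE 0.20, adjusted p = 0.0336). Ciart and Per2 were above background on 2 of the 3 MCU knockout arrays. These 3 repressors passed over all probe sets, but of 19 other settings Cry2 was lost in 13, Per2 in 10 and Ciart in 1. Adjusted over the list alone 7 genes were lower (with Dbp, Per1, Hlf and Tef) and 3 higher (Clock, Arntl and Nr1d1), and fry gave an adjusted p of 0.0372 for a shift one way and of 1.88e-06 for change in either direction.

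**Figure D2:**
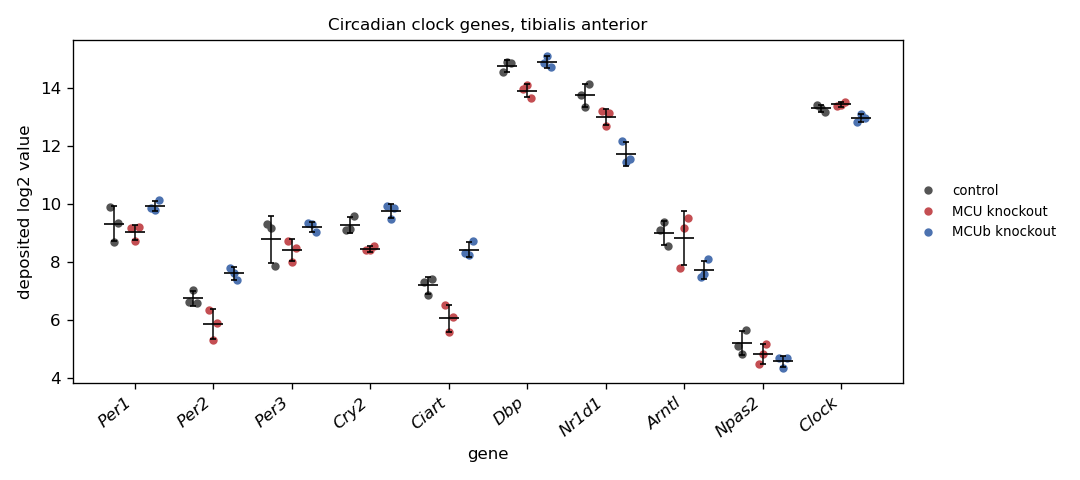
Deposited log2 values (vertical axis) of 10 clock genes on each of the 9 arrays, by genotype; points are arrays, bars the mean and SD of 3 arrays, and Per1, Per3, Arntl, Npas2 and Clock were chosen after their values were seen. Per2, Cry2 and Ciart lie lower in the MCU knockout than in the MCUb knockout (-1.75, -1.30 and -2.37), and Arntl, which did not pass, lies higher (1.10).

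Fibroblast and matrix genes were higher in the MCU knockout than in the MCUb knockout, 18 of 19 of them, with a median of 0.30 (camera adjusted p = 0.0105, and adjusted p = 0.90 with an estimated correlation). Col5a1 was at 1.02 (SE 0.32, adjusted p = 0.57), Sparc at 0.62 and Col6a2 at 0.42. No member passed in limma, 0 over all probe sets and 0 adjusted over the list alone, with 2 higher at an unadjusted p under 0.05. The mean log2 level of these genes was 9.44 and 9.18 on the MCU knockout arrays with high Y-linked levels and 8.43 on the remaining one. In the MCUb knockout it was lowest on the array with a high Y-linked level, at 8.34, against 8.83 and 8.96. With that level as a covariate the list stayed higher in the MCU knockout (adjusted p = 0.0450). On the arrays where the level was low, with a single MCU knockout array among them that is assumed to vary like the other groups, the list was lower (adjusted p = 0.00878). The call was lost without MCU knockout replicate 2 (0.469), MCU knockout replicate 3 (0.119) or MCUb knockout replicate 1 (0.356), and over 16 alternatives the adjusted p ran from 2.44e-08 to 0.899.

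In the uniporter list 9 of 11 genes were lower in the MCU knockout than in the MCUb knockout, with a median of -0.088 and a mean of -0.47 (camera adjusted p = 0.0193, and adjusted p = 0.27 with an estimated correlation). This list holds the deleted gene. Without Mcu the other 10 genes had a mean of -0.12 and did not pass (camera adjusted p = 0.464, fry 0.755). Mcu alone passed as a gene, and Mcur1, a regulator of the uniporter, was at -0.48 (SE 0.17, adjusted p = 0.683). The other 29 lists had adjusted p-values between 0.209 and 0.965. Pdk4 at 1.87 (SE 0.36, adjusted p = 0.112), Ucp3, an uncoupling protein, at 1.92 (SE 0.39, adjusted p = 0.135) and Cldn5 at 1.76 (SE 0.33, adjusted p = 0.098) were higher in the MCU knockout adjusted over the list alone, and Ndufa3 at -0.93, Stim1 at -0.87 and Srxn1 (at least 1.75-fold, not well above background in the MCU knockout) were lower. The uniporter list was lost with the filter on dim probe sets (0.0802), after quantile normalization (0.0533) and without MCU knockout replicate 1 (0.0625), MCU knockout replicate 3 (0.057) or MCUb knockout replicate 2 (0.0892), within a range of 0.00729 to 0.464 over 17 alternatives.

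The changes in the knockouts were correlated across probe sets, which share their 3 controls and are not independent replicates. Pearson's r between the MCU and the MCUb knockout was 0.621, and simulated unchanged groups against shared simulated controls gave 0.620 on average (0.598 to 0.644 in 100 simulations). The simulated noise was independent between probe sets. Noise shared between probe sets could widen the simulated ranges, so they cannot judge an excess. Leaving out single arrays moved r beyond that range, but it also changes the group sizes and so the r met with no effect. It therefore does not tell how wide the range should be. The covariance was 0.0785 against a simulated 0.0553 (0.0522 to 0.0603), a difference of 0.0232, and 73.6% of probe sets had the same sign against 70.5% (69.7% to 71.4%). The probe sets past the threshold in the MCU knockout and those in the MCUb knockout had 0 in common in either direction, where independent lists would share 0.00126 higher and 0.0023 lower. Too few controls were measured to split them, so part or all of the difference in covariance may come from the shared controls.

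**Figure D3:**
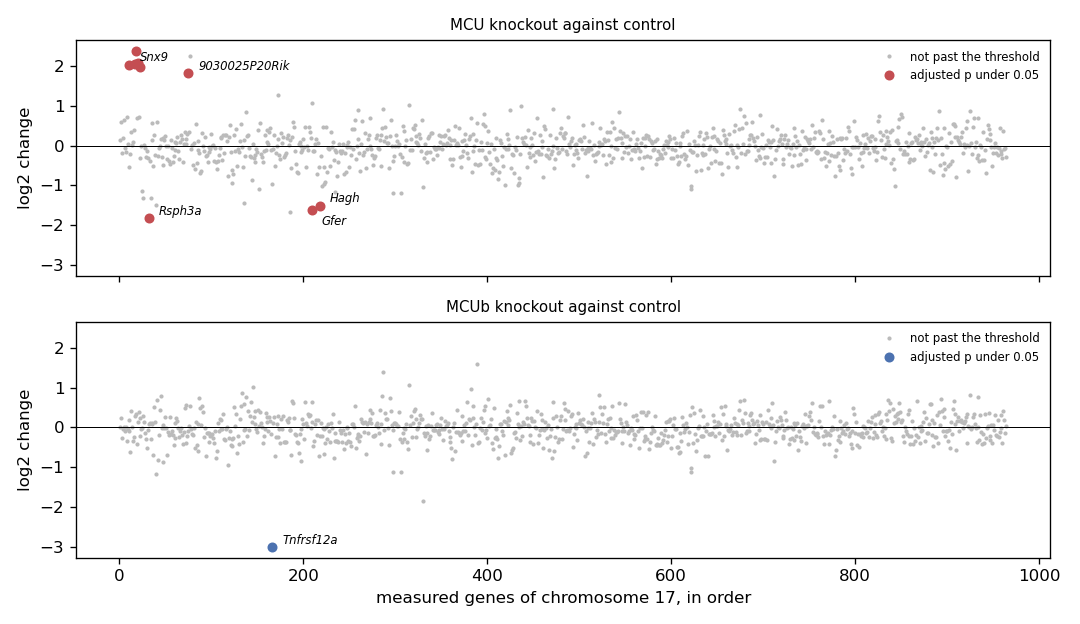
Log2 change against control (vertical axis) of the 964 measured genes of chromosome 17 in chromosomal order (horizontal axis, order only), in the MCU knockout (upper panel) and the MCUb knockout (lower panel); coloured points passed an adjusted p of 0.05. The MCU knockout has 9 such genes on this chromosome, which was picked for holding the most of them, and the MCUb knockout 1, Tnfrsf12a.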

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

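The splits of the samples were laid down beforehand, while the tests of the clock genes were chosen only after the result was seen. In the direct comparison 35 probe sets differed between the MCU and the MCUb knockout, a difference between groups tested in limma. In fits of those 6 arrays alone the real split gave 39 and the highest other split 28, so 1 of the 10 splits gave as many, and 10 splits cannot give a share under 0.05. The split with 28 set MCU knockout replicates 2 and 3 and MCUb knockout replicate 1 against the rest, which is the split by Y-linked level. With that level as a covariate in the fit of all 9 arrays, 25 probe sets passed. For MCU knockout against control, 1 of 10 splits gave as many as the real 21 probe sets (highest other 0). For MCUb knockout against control, 1 of 10 gave as many as the real 1 (highest other 0). These shares cannot fall under 0.05 either.

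For gene lists in fits of 6 arrays, 3 of the 10 splits gave as many as the real 3 between MCU knockout and control (highest other 8), and 10 of 10 as many as the real 0 between MCUb knockout and control (highest other 6). Between the knockouts 6 of 10 gave as many as the real 3 (highest other 8). Again 10 splits cannot give a share under 0.05. With an estimated correlation 0 lists passed in the real splits and in all others, so these counts rest on the preset correlation, and whether a structure of the samples adds to them stays open.

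The uniporter list differed between the knockouts with a median of -0.088, and Mcu was its only member past the threshold. Without Mcu, a setting chosen after seeing the data, the list did not pass (adjusted p = 0.464, in a range of 0.00729 to 0.464 over 17 alternatives). Fibroblast and matrix genes differed between the knockouts with a median of 0.30 over all 9 arrays, and in the opposite direction on the arrays with low Y-linked levels, among them a single MCU knockout array (adjusted p = 0.00878). With the Y-linked level as a covariate they stayed higher in the MCU knockout (adjusted p = 0.0450, in a range of 2.44e-08 to 0.899 over 16 alternatives).

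Clock genes differed between the knockouts with a median log2 difference of -0.66. The repressors Per1, Per2, Per3, Cry2 and Ciart were set against Arntl, Npas2 and Clock, which peak at another time of day. These arms moved in opposite directions between the knockouts and in the MCUb knockout against control, while in the MCU knockout against control both means were lower (-0.70 and -0.14). The difference between the arms was -2.03 (SE 0.32) between the knockouts and 1.46 (SE 0.32) in the MCUb knockout against control, each with p = 0.1 in an exact two-sided permutation test, the smallest that 3 arrays against 3 allow. In the MCU knockout against control it was -0.57 (SE 0.32, exact permutation p = 0.4). Uneven sex of the arrays is argued against as the whole cause, since the list stayed past the threshold with the Y-linked level as a covariate (adjusted p = 3.40e-07, in a range of 3.40e-07 to 0.224 over 16 alternatives). A difference in the time of day at harvest is a candidate explanation that stays open: the arms were chosen after their values were seen and hold Per2, Cry2 and Ciart, already past the threshold, so their opposition tests nothing, and the labels give no harvest time. Nr1d1, in neither arm, was at -2.02 in the MCUb knockout against control. Loss of MCU or of MCUb acting on the clock cannot be told apart from harvest time, because the labels do not separate them: 5 of the 6 knockout arrays lay beyond the range of the controls, -0.984 to -0.756, in the direction of their group. MCU knockout replicate 1, at -0.718, lay on the other side, so it lacked the MCU knockout's shift between the arms.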

How the results depend on the processing

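Among named genes and the lists past the threshold in the main fit, 6059 of 6218 values were kept, 147 lost significance, 11 gained it and 1 reversed. Kept means the same side of the threshold, and a change of sign between values that both did not pass counted as kept. Most of these values belong to genes that did not pass in the main fit and count as kept while they stay so. The share kept therefore does not measure how stable the calls are. Lists that passed only under another setting are not in these counts. Among the results that answer a comparison, 144 of 182 were kept. There a count within 1.5-fold of the main one counted as kept, as did a correlation that moved by less than the SD of its leave-one-out values. Quantile normalization, centring and an intensity trend each lost 1 of the 32 named calls. The Y-linked level as a covariate lost 10, leaving out MCU knockout replicate 3 lost 13, and leaving out MCUb knockout replicate 3 lost 11. Under any setting 0 named calls changed sign. In these calls the groups compared did not overlap, so leaving out or weighting arrays could not turn a sign, and that count is no check there. Where no cause is named, the cause was not tested. With the Y-linked level as a covariate, chosen after seeing the data, 16 probe sets passed between MCU knockout and control instead of 31. On the 6 arrays with low Y-linked levels, also chosen after seeing the data, 0, 0 and 3 passed in MCU against control, MCUb against control and MCU against MCUb (limma, 1090, 1117 and 912 at an unadjusted p under 0.05), and the change of Mcu, -3.80, had an adjusted p of 0.0794, in a range of 1.34e-05 to 0.0794 over its alternatives. That setting has fewer samples. The 31 changes past the threshold between MCU knockout and control were 0.835 to 1.22 times their size there, while their median SE went from 0.22 to 0.32. Their sign was fixed in advance, since in these genes no MCU knockout array overlapped with the same controls. The lone MCU knockout array of that setting is assumed to vary like the other groups. A fit of the 2 groups alone, also with fewer samples, gave 1 between MCUb knockout and control instead of 5. Array quality weights gave 61 between the knockouts instead of 35. With 1 array left out the counts ranged from 20 to 98, from 0 to 20 and from 13 to 43 in the order above, where fewer samples entered. The highest of the first and second came without control replicate 2. The lowest of the second came without control replicate 1, MCUb knockout replicate 1 or MCUb knockout replicate 3 (limma, 1649, 1395 and 1436 at an unadjusted p under 0.05).

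Lists past the threshold between MCU knockout and control numbered 1 by fry, 0 with an estimated correlation (1 at an unadjusted p under 0.05), 1 with the Y-linked covariate, 1 on the arrays with low levels, and 1 to 4 with an array left out, instead of 2. Between MCUb knockout and control they numbered 2 with the filter on dim probe sets, 1 after quantile normalization, 1 on the arrays with low levels, and 0 to 1 with an array left out, instead of 0. Between the knockouts they numbered 0 with an estimated correlation (2 at an unadjusted p under 0.05), 7 on the arrays with low levels, and 1 to 6 with an array left out, instead of 3. Fibroblast and matrix genes reversed between the knockouts on the arrays with low levels, where 1 MCU knockout array remained (adjusted p = 0.00878, in a range of 2.44e-08 to 0.899). The uniporter list between the knockouts did not pass without Mcu (adjusted p = 0.464), a setting chosen after seeing the data. The correlation of the knockouts' changes ranged from 0.549 (without MCUb knockout replicate 1) to 0.759 (without control replicate 2). Same-numbered arrays did not deviate together (r of -0.121 to 0.0882, against -0.118 to 0.0929 for other pairs). That gives no sign of a pairing by number but cannot exclude one. With the replicate number as a block 24, 5 and 28 probe sets passed.

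Calls that were lost most often were Cry2 (13 of 19 settings), Nr1d1 (11), Gpr19 (10), Per2 (10), Gfer against control (10), Tnfrsf12a between the knockouts (10) and Cep85l (8). Clec3b was kept in all 19. Signal over background limits Gpr19 and Serpina3n to bounds, and Vmn2r29, Clec3b, Ciart and Per2 were above background on only part of the MCU knockout arrays.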

Other observations

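The test of genes near Mcu was laid down beforehand, while the tests of chromosomal neighbours and of genes near Mcub were chosen only after the result was seen. Some metabolic genes outside the naming rule passed the threshold, and those named in this paragraph were chosen after their values were seen. Galt, galactose-1-phosphate uridylyltransferase, fell from 9.69 ± 0.15 (SD, n = 3) to 8.16 ± 0.17 in the MCU knockout (log2 change -1.53, SE 0.18, adjusted p = 0.00500). Hagh, which hydrolyses the glutathione thioester of the glyoxalase pathway, fell from 11.47 ± 0.26 to 9.96 ± 0.31 (adjusted p = 0.0205), and the ectonucleotidase gene Entpd1 from 9.11 ± 0.35 to 7.58 ± 0.34 (adjusted p = 0.0458). The spindle protein gene Ska2 rose at least 1.55-fold, from 5.14 ± 0.11, not well above background, to 6.53 ± 0.14. Ppm1k, the phosphatase that activates branched-chain ketoacid dehydrogenase, was lower in the MCU knockout than in the MCUb knockout (8.41 ± 0.30 against 9.67 ± 0.09, adjusted p = 0.0489), as was Adh1 (11.51 ± 0.27 against 13.06 ± 0.13, adjusted p = 0.0119). The unnamed probe set TC0Y00000223.mm.2 was at 14.46 ± 0.75 in the MCU knockout and 9.82 ± 0.44 in the MCUb knockout (adjusted p = 0.000733).

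Many genes past the threshold in the MCU knockout were chromosomal neighbours. Of the 29 named, 19 lay in 6 clusters on 5 chromosomes. On chromosome 17 these were Snx9, Dynlt1a, Dynlt1b, Dynlt1c, Dynlt1f, Rsph3a and 9030025P20Rik in the first cluster and Gfer with Hagh in the next. Pdlim1 lay beside Entpd1 on chromosome 19, Myorg with Galt and Gm3893 on chromosome 4, Gpr19 with Plbd1 on chromosome 6, and Gadd45gip1 with the overlapping pair Wdr83 and Wdr83os, uncertain as separate genes, on chromosome 8. Chromosome 17 held 9 of the 29, where 1.43 would fall to it by its 964 measured genes. It was picked as the chromosome with the most, and its 9 include the near-identical Dynlt1 copies, so this contrast is overstated. Against the MCUb knockout 13 of the 19 passed too, in a comparison that uses the same MCU knockout arrays and so is not independent of the first. The pair on chromosome 19 lay below control in the MCUb knockout as well: Pdlim1 and Entpd1 were at -1.30 and -1.29 against control there, and differed between the knockouts by -0.47 and -0.25 (adjusted p of at least 0.942). In 4 of the 6 clusters every member fell. In the other 2 members went both ways: Snx9 rose by 2.04 and Rsph3a fell by 1.82, and Myorg rose by 2.76 beside Galt at -1.53.

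Neighbours within 50 measured genes whose symbols differ only in a last letter or an os suffix were merged. After that, 15 of 25 had another within 50 measured genes, against a mean of 2.97 and a highest of 14 in random draws. These were 10000 draws matched on expression (permutation p = 1e-04, the smallest they can give). The 29 merged genes of smallest p in the MCUb knockout had 6 (mean 3.90, permutation p = 0.285). Only 4 named probe sets passed there, so most of the 29 were not past the threshold. They do not show whether clustering is particular to the MCU knockout. Cross-hybridisation among like-named copies is argued against as the whole cause by the 60% of merged genes that kept a neighbour. Sequences were not compared, so near-identical neighbours with unlike names stayed separate, and for them it stays open. Uneven sex of the arrays is argued against as the whole cause, since 6 of 11 merged genes called with the Y-linked level as a covariate had another near (random mean 0.545, permutation p = 0.001). Chromosome segments of another strain, or of another copy number, are a candidate explanation, which the clustering fits, though for the chromosome 19 pair no difference between the lines was shown. Loss of MCU itself acting on these genes cannot be told apart from it: on the neighbouring genes called without it, each MCU knockout array lay at a median position of 0.946, 0.854 and 1.01 in replicate order (quartiles 0.463 to 1.08 for replicate 1; 0 at the control mean, 1 at the mean of the other MCU knockout arrays), so 0 of them carried the knockout without the changes.

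A segment kept around a deleted gene during breeding could change its neighbours, so the 200 measured genes nearest each deleted gene were examined. They were set against 87 windows of 200 genes laid along all chromosomes, without leaving out the regions of the deleted genes or of the clusters. Around Mcub on chromosome 3, 15 had an unadjusted p under 0.05 in the MCUb knockout, against a median of 16 and a highest of 30. Around Mcu on chromosome 10, 19 did in the MCU knockout, against a median of 19 and a highest of 40. Neither count argues for a flanking segment with many changed genes. The test sees only part of such segments: windows around the 6 clusters held 23 to 40, and 3 of the 6 exceeded the 95th percentile of 28.7. The clusters themselves can raise that percentile, since their regions were not left out of the 87 windows. Adh1 was the only gene past the threshold near Mcub, the 85th nearest, and a linked change in that gene alone stays open.

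Control features of the arrays, left out of the comparisons, had 0 past the threshold in limma in each comparison (626, 567 and 261 of 6640 at an unadjusted p under 0.05, the last between the knockouts, where chance gives 332).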
